A study of Neurospora crassa with 2 samples.

How the data were processed

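The series compares a wild-type strain of Neurospora crassa with a upf1 knockout strain. Per the labels, hyphae came from cultures in 2% glucose medium kept in constant light for 2 days after 2 weeks on slants, RNA from 3 independently grown flasks was pooled per strain, and polyadenylated RNA was sequenced by standard Illumina library methods. Each strain is therefore 1 pooled sample. Columns of the deposited table were assigned to strains by their names, which begin with the initials of the sample titles, and no column of values was left unassigned.

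The deposited table gives raw read counts and RPKM values for 9454 genes of both libraries, per the file headers. The authors' RPKM values are reads per kilobase of gene model, scaled to the total of each library. These totals were recovered by dividing reads by RPKM, and 94.4% of the knockout total and 95.4% of the wild-type total are in the table. Bowtie 0.12.2 is named in the submitters' processing notes. The genome build, the annotation version, the counting method, the use of strand, and the treatment of reads that map to several genes are not given in the sources used here, so overlapping genes and close paralogues are uncertain. The gene model length implied by reads and RPKM differed between the libraries for 95 of 7359 genes with more than 100 reads in each (1.29%, tolerance 0.1%). Coordinates are those of the deposited table.

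Gene identifiers were matched to a RefSeq gene table of assembly NC12, used for names only; 8942 of the 9454 identifiers matched and 1112 had a symbol. The upf1 gene has the symbol prd-6 there. No genome sequence was used.

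The main measure was log2((knockout RPKM + 1)/(wild-type RPKM + 1)), with a pseudocount of 1 and without rescaling. Genes with at least 5 RPKM in at least 1 library were eligible, and a gene was counted as higher or lower from 2-fold on this scale. Folds printed in the text are ratios of reads over the library totals without the pseudocount. They equal the ratio of the RPKM values unless the gene model length differed between the libraries, as for NCU00732, NCU06326, cdh-2 and NCU05859 among the genes in the text. Their 95% intervals are exact Clopper-Pearson intervals of the gene's share of its summed reads, turned into ratios with the library totals. Reads without molecular identifiers are not independent molecules, so the intervals cover counting error only and say nothing of variation between cultures. Depth was 56306422 table reads in the knockout and 28189643 in the wild type. A count of 0 allows up to 3 reads, which for a gene of 1 kb is 0.0503 RPKM in the knockout and 0.102 RPKM in the wild type. Eligible genes had a median of 3052 and 1336 reads.

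With 1 library per strain no test between strains can be made and no p-value is given. Before the data were examined, 22 gene lists were fixed by symbol and product name. They cover nonsense-mediated decay and the exon junction complex, the clock, clock-controlled genes, light response and carotenoids, conidiation, mating and sexual development, amino acid biosynthesis, cytosolic and mitochondrial ribosomal proteins, the respiratory chain, glycolysis and the TCA cycle, splicing, RNA decay, heat shock, oxidative stress, carbohydrate-active enzymes, cell wall synthesis, nitrogen, sulfur and phosphate regulation, sugar transporters, DNA repair and replication, the proteasome, and lipid and sterol synthesis. The conidiation and the mating lists stand for other cell types. The median of a list was placed by percentile among 10000 random lists of the same size drawn from 20 bins of mean expression. A list was said to stand apart in the top or bottom 2.5%, as a description of these libraries. Lists with at least 5 eligible members were described. Hypothetical proteins were treated in the same way. Planned classes defined by untranslated regions, upstream reading frames or coding sequences free of introns need a genome annotation and were not analysed here. A split of gene models by introns, read from a genomic span longer than the length behind RPKM, was added after the data were seen.

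The rule for named genes, fixed before the data were examined, took upf1, the 10 largest and 10 smallest log2 ratios, 11 clock, decay and upstream-reading-frame genes whatever their value, and up to 4 members with a symbol per list by size of the log2 ratio. Of the 11, the decay genes upf2 and upf3 matched no symbol. The rule gave 108 genes, of which 13 overlap another gene model and 105 have a counting interval excluding a ratio of 1. Other names (prd-4, ck-1b, phr, con-10, con-13, fl, nit-3, nit-6, arg-3, leu-1, lys-5, lys-6, lys-7, gdh-1, stk-24, cyt-21, nmt-1, pks-5, matA-1, matA-2, matA-3, NCU00413, NCU02757, NCU05267, NCU06110, NCU08388, NCU09703, NCU09992, NCU10538, NCU_16005, NCU_16016 and NCU_16024) were added after their values were seen.

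Alternatives fixed in advance were pseudocounts of 0.1 and 5, no filter and a filter at 20 RPKM, centring on the median gene, TMM scaling of the counts (edgeR 4.0.16 in R 4.3.3), rules of 1.5-fold and 4-fold, the 2-fold rule with a counting interval excluding a ratio of 1, and list members by symbol alone. Added after seeing the data were centring within 20 bins of gene model length, random lists matched on expression and length (10 by 6 bins), thinning of the knockout reads to the wild-type total, totals without the 2 most abundant genes, one shared length per gene, the respiratory list without mitochondrially encoded genes, the glycolysis and TCA list without products outside these pathways, the carbohydrate-active list without products named for chitin, 1,3-glucans or glycans, the cytosolic ribosomal list with 40S and 60S names borne once, and the clock-controlled, light and conidiation lists without shared members. Python 3.11.15 with NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and Matplotlib 3.10.9 was used. The counting and list steps were tested on simulated counts for 9454 genes with 200 genes changed 3-fold: 100 of 100 raised and 93 of 100 lowered genes were recovered, 0 of 6973 unchanged eligible genes were called, and 8 of 200 unchanged lists stood apart. The spread given to the simulated libraries was small and set by choice, without a length trend or genes that change together. These numbers therefore check the steps and are not error rates of the comparison.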

Results

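RNA sequencing was used to compare a wild-type strain of Neurospora crassa, a filamentous ascomycete fungus, with a strain lacking upf1. UPF1 is the RNA helicase at the centre of nonsense-mediated mRNA decay, the pathway that degrades transcripts with premature or unusually placed stop codons. Hyphae were grown for 2 days in 2% glucose medium in constant light, and polyadenylated RNA from 3 separately grown flasks was pooled for each strain. There was 1 library per strain. The knockout library held 56306422 reads and the wild-type library 28189643 reads over 9454 genes, and the library totals behind the normalised values differed 2.02-fold. A gene had a median of 2049 reads in the knockout library and 862 in the wild-type library, and 81 genes had no read in either. With 1 pooled library per strain no difference has a replicate check. No p-value was calculated, and the 95% intervals printed beside ratios are exact Clopper-Pearson intervals that cover counting error only.

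The comparison asks which transcripts differ in abundance when UPF1 is missing, and whether those of the circadian clock are among them. The targeted gene was examined first. Its entry NCU04242 (RefSeq symbol prd-6, product ATP-dependent helicase NAM7, the budding yeast name of UPF1) lies on the minus strand of supercontig 5 from 5328106 to 5332056, in the coordinates of the deposited table, whose genome build is not given in the sources used here. It stood at 2.78 RPKM (reads normalised for gene model length and library total) from 654 reads in the knockout library and at 22.6 RPKM from 2641 reads in the wild-type library. This is 8.15-fold lower in the knockout library (7.48 to 8.89), in the direction of the labels. Which part of the gene the knockout removed is not given in the sources used here, so the remaining reads cannot be placed inside or outside it.

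Of the 7367 genes with at least 5 RPKM in at least 1 library, 1214 (16.5%) were at least 2-fold higher in the knockout library and 407 (5.52%) at least 2-fold lower, while 5746 lay within 2-fold. Counts of higher and lower list members given below are to be read beside these shares. At 4-fold the numbers were 285 and 99. Ratios are on the scale of log2(RPKM + 1), which understates differences of weakly expressed genes. The median log2 ratio over all eligible genes was 0.15 (interquartile range across genes -0.28 to 0.69), and it moved to -0.020 with TMM scaling, so values near it have no firm sign. Genes on the higher side made up 74.9% of those past 2-fold, against 64.1% after centring on the median gene, 62.6% with TMM scaling and 58.6% after centring within bins of gene model length. Shorter gene models had higher ratios: the median went from 0.56 in the shortest eighth (36 to 935 bp) to -0.10 in the longest (3104 bp and above). Below, length centring means that the median ratio of its length bin was subtracted from each ratio, which also removes the overall offset.

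**Figure D1:**
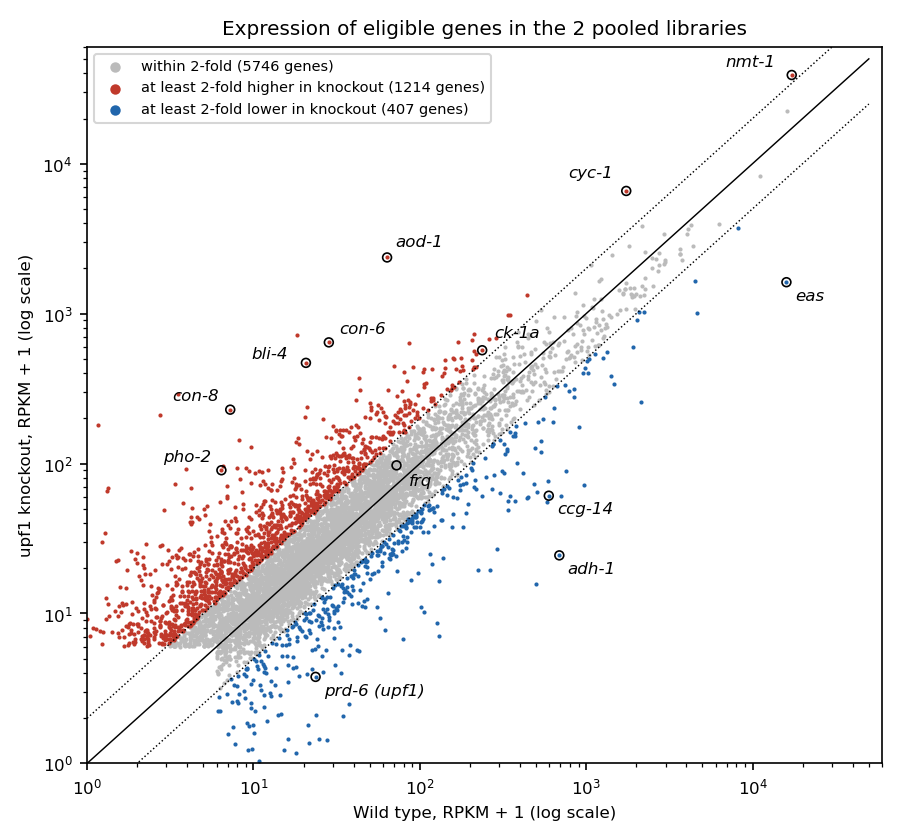
RPKM + 1 of each eligible gene in the wild-type library (horizontal, log scale) and the upf1 knockout library (vertical, log scale), with 1 pooled library per strain. The solid line marks equal values and the dotted lines 2-fold, with 1214 genes above the upper dotted line, 407 below the lower one, and circles on genes named in the text.

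**Figure D2:**
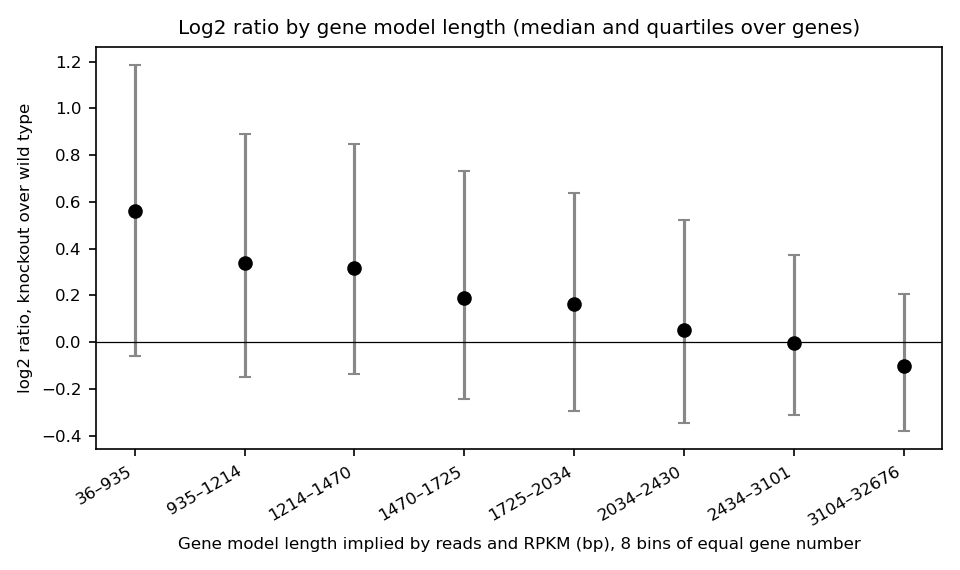
Median log2 ratio of knockout over wild type (vertical) in 8 bins of gene model length in bp (horizontal), with bars for the interquartile range across genes. The median goes from 0.56 in the shortest bin to -0.10 in the longest.

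Among clock genes, ck-1a had the largest ratio on the higher side. This gene encodes casein kinase I, which phosphorylates the clock protein FRQ, and it stood at 569 RPKM in the knockout library and 236 in the wild-type library, 2.41-fold higher (2.37 to 2.45). It lies on the plus strand of supercontig 1 from 7563398 to 7566370. The related gene ck-1b had 253 and 189 RPKM. Transcripts of frq, the central negative element, were 1.35-fold higher (1.31 to 1.39; 96.2 against 71.4 RPKM), and those of wc-2, a subunit of the white collar photoreceptor and transcription complex, 1.59-fold higher (1.52 to 1.67). The blue-light photoreceptor gene vvd was 1.60-fold higher (1.59 to 1.62; 1366 against 852 RPKM). For wc-1 the libraries gave 17.5 and 17.2 RPKM, and the counting interval of the ratio, 0.965 to 1.07, included 1. That interval holds for the deposited scaling only: the log2 ratio of wc-1 was 0.02, but 0.18 with length centring. The FRQ-interacting helicase gene frh was 1.18-fold lower (1.13 to 1.24) and fwd-1, whose F-box protein takes part in FRQ degradation, 1.26-fold lower (1.20 to 1.33). The log2 ratios of frq (0.43), wc-2 (0.65), vvd (0.68), wc-1 and frh (-0.23) lay within the interquartile range across all eligible genes, -0.28 to 0.69. The checkpoint kinase gene prd-4 had 23.5 RPKM in the knockout and 36.2 in the wild type. As a group the 30 clock genes, prd-6 among them, did not stand apart: their median log2 ratio of -0.05 lay at percentile 13.5 of 10000 random lists matched on expression (-0.11 at 35.8 with length centring), with 2 members, ck-1a and the COP9 signalosome gene NCU08388, at least 2-fold higher and 1, prd-6 itself, at least 2-fold lower.

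**Figure D3:**
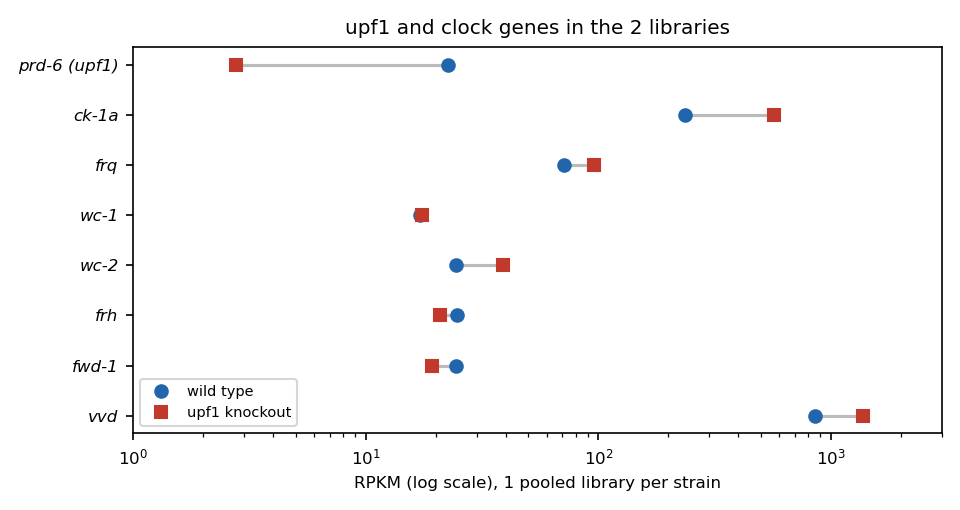
RPKM (horizontal, log scale) of prd-6 (upf1) and clock genes in the wild-type library (circles) and the knockout library (squares), 1 pooled library per strain and no error bars. prd-6 goes from 22.6 to 2.78 RPKM and ck-1a from 236 to 569, while both wc-1 values lie close together at 17.2 and 17.5.

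The 6 eligible genes of nonsense-mediated decay and the exon junction complex lay within 2-fold, with a median of 0.02 at percentile 37.7 (0.03 with length centring) that turned negative with TMM scaling. The list was matched by product name and also holds the cap-binding products NCU00210 and NCU04187. It does not hold prd-6 (upf1) itself, which was counted among the clock genes. NCU05267, annotated as a nonsense-mediated mRNA decay factor, had 23.2 RPKM in the knockout and 21.9 in the wild type. NCU08663, with the product name nonsense-mediated mRNA decay protein 3, had 44.3 and 50.3. A product name alone does not show that a gene acts in decay. No entry carried the symbol upf2 or upf3. The remaining RNA decay and exosome genes had 2 of 19 members higher and none lower, with a median of 0.13 at percentile 57.0 whose sign was also lost with TMM scaling and with length centring. NCU08026, a 3' exoribonuclease, was 2.49-fold higher (2.39 to 2.59), and the exosome gene NCU04155 2.15-fold higher (2.03 to 2.28), although its log2 ratio of 1.08 fell below the 2-fold rule with median centring, TMM scaling and length centring (0.74). Of 65 pre-mRNA splicing genes, 7 were higher and none lower, and the median of 0.28 lay at percentile 96.5, inside the central range of random lists (0.06 with length centring). The splicing factor gene NCU08395 (Dim1) was 6.60-fold higher (6.26 to 6.95).

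Light-responsive and carotenoid genes stood apart on the higher side. Of 20 eligible members, 8 were at least 2-fold higher and 1 lower, with a median of 0.65 at percentile 99.8. The blue-light-induced gene bli-4 was 23.8-fold higher (22.1 to 25.7) and al-1, which encodes the phytoene desaturase of carotenoid synthesis, 3.17-fold higher (3.11 to 3.24). The opsin gene nop-1 stood at 6.27 against 0.925 RPKM, short of 2-fold with a pseudocount of 5, and the photolyase gene phr at 107 against 35.0 RPKM. The member on the lower side was eas, the gene of the rodlet hydrophobin that coats conidia. It stood at 1619 RPKM in the knockout and 15983 in the wild type, 9.87-fold lower (9.80 to 9.95).

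Clock-controlled genes divided. Of 13 eligible members, 3 were higher and 3 lower, and the median of -0.43 lay at percentile 4.88 of expression-matched lists, and at 0.75 once lists were also matched on gene model length, but with length centring it was -0.67 at 5.35, so that the list stood apart under one of these only. The conidiation gene con-6 was 23.4-fold higher (21.7 to 25.4; 642 against 27.4 RPKM), whereas ccg-14 was 9.92-fold lower (9.56 to 10.3) and eas is counted here too. Conidia can form on hyphae, and the 15 eligible conidiation markers, which share con-6, con-10 and eas with both preceding groups, differed in both directions. 5 were higher and 4 lower, with a median of 0.14 at percentile 44.6 (0.23 for members matched by symbol) that turned negative with TMM scaling. con-8 was 36.4-fold higher (31.9 to 41.8), and con-13 stood at 5.56 against 1.12 RPKM. The conidiation regulator gene fl stood at 17.7 RPKM in the knockout and 47.2 in the wild type. acu-6, the gene of the gluconeogenic enzyme phosphoenolpyruvate carboxykinase, entered this group through a con-type synonym and was 5.96-fold higher (5.52 to 6.43). Of the 15 eligible mating and sexual development markers, 2 were higher and 2 lower, with a median of -0.08 at percentile 6.92 (-0.17 with length centring). asd-1, which encodes a rhamnogalacturonase, was 4.60-fold higher (4.31 to 4.92) and poi-2 was 4.59-fold lower (3.61 to 5.89), short of 2-fold with a pseudocount of 5.

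Amino acid biosynthesis genes stood apart on the lower side: of 67 members 16 were lower and 2 higher, with a median of -0.61 below that of all 10000 random lists. The 2 higher members were gdh-1, the gene of the NAD-specific glutamate dehydrogenase, which breaks glutamate down, and NCU09703, an acetolactate decarboxylase gene, neither of which makes an amino acid. The homoserine kinase gene thr-4 was 4.32-fold lower (4.01 to 4.66) and the arginine biosynthesis gene arg-5 3.04-fold lower (2.92 to 3.17). his-6 and arg-12, 4.10-fold and 3.47-fold lower, overlap neighbouring genes, and whether reads were counted by strand is not given, so their values are uncertain. arg-2, whose upstream reading frame encodes the arginine attenuator peptide, stood at 167 RPKM in the knockout and 187 in the wild type. cpc-1, the transcription factor gene of cross-pathway control, was 1.73-fold higher (1.71 to 1.74). Cytosolic ribosomal protein genes also stood apart on the lower side, with a median of -0.46 (-0.79 with length centring) below all random lists, although only 5 of 88 were 2-fold lower and 1 was higher. Matching by name also took in cyt-21, a gene of the mitochondrial ribosome, and second genes of the same protein name, as for L2 (NCU02757, log2 ratio 1.16, beside NCU00413 at -0.57). The 48 members with a 40S or 60S name borne once, 4 lower and none higher, had a median of -0.56 at percentile 0.03. crp-2 was 2.41-fold lower (2.37 to 2.45). Mitochondrial ribosomal protein genes stood apart on the opposite side, with 5 of 30 higher, none lower and a median of 0.68 at percentile 99.97. With length centring the median was 0.30, still apart at 99.7. NCU06450 was 2.35-fold higher (2.25 to 2.44).

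Energy metabolism showed the alternative oxidase among the largest differences. aod-1, which encodes the enzyme that bypasses respiratory complexes III and IV, stood at 2368 RPKM in the knockout and 62.6 in the wild type, 37.8-fold higher (36.5 to 39.3), on the plus strand of supercontig 4 from 1235252 to 1236932. Its paralogue aod-3 stood at 23.0 RPKM in the knockout and 2.25 in the wild type, and the cytochrome c gene cyc-1 was 3.78-fold higher (3.74 to 3.82). Genes of the mitochondrial genome were mostly on the lower side, by unequal amounts: cox2 (NCU_16028) was 31.6-fold lower (23.6 to 43.2) and cox3 (NCU_16003) 103-fold lower (51.9 to 241), from 8 reads in the knockout library, but subunit 1 of the same enzyme (NCU_16016) 5.41-fold (3.8 to 7.84) and ATPase subunit 8 (NCU_16024) 1.75-fold lower (1.11 to 2.75), while NCU_16005, a ribosomal protein gene, had 66 reads in the knockout and 13 in the wild type. The list of respiratory chain and ATP synthase genes, 5 of 64 higher and 6 lower, did not stand apart. Its median of 0.14 lay at percentile 86.2 and its mean was -0.03, and with TMM scaling or length centring the median too was negative. All 6 lower members are mitochondrially encoded: the 58 nuclear members, 5 higher and none lower, had a median of 0.16 at percentile 95.7, still not apart, and a mean of 0.35. Glycolysis and TCA cycle genes had 8 of 37 members lower and 2 higher, with a median of -0.25 at percentile 1.54, but 5.24 with length matching and 6.55 (-0.39) with length centring. The 8 members matched by symbol, hex-1 and arg-3 among them, had a median of -1.42, below all random lists. The enolase gene emp-7 was 4.60-fold lower (4.57 to 4.63; 1001 against 4610 RPKM). Phosphoglycerate kinase (pgk) was 3.03-fold lower but overlaps a neighbouring gene. hex-1, which encodes the major protein of the Woronin body, an organelle that plugs septal pores, belongs to this group by its symbol only. It was 3.17-fold lower and also overlaps a neighbour. Another of the 8, arg-3, encodes a subunit of carbamoyl-phosphate synthase of arginine biosynthesis, and the 2 higher members were tca-2, annotated as a 2-methylcitrate synthase, and stk-24, a pyruvate dehydrogenase kinase gene. In all 11 of the 37 encode no enzyme of these pathways, leu-1, lys-5, lys-6 and lys-7 of leucine and lysine synthesis among them. The other 26, with 6 lower and none higher, had a median of -0.12 at percentile 19.9 and did not stand apart.

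Oxidative stress and detoxification genes stood apart on the higher side, with 10 of 38 higher and none lower and a median of 0.63 at percentile 99.98. It was 0.28 with length centring and 1.03 for the 8 members matched by symbol, and the list stood apart in both. The catalase-peroxidase gene cat-2 was 10.1-fold higher (9.24 to 11.1), the catalase gene cat-3 2.85-fold higher (2.76 to 2.93) and the superoxide dismutase gene sod-2 2.46-fold higher (2.32 to 2.61), below the 2-fold rule with length centring (log2 ratio 0.93 in place of 1.28). Heat shock and chaperone genes did not stand apart. 6 of 34 were higher and 2 lower, and their median of 0.03 at percentile 32.9 had no firm sign, being negative with TMM scaling, with length centring and for members matched by symbol. The mitochondrial chaperone gene hsp78 was 5.64-fold higher (5.31 to 5.99), while the hsp70 genes hsp70-1 and hsp70-2 were 1.67-fold and 2.04-fold lower. The hsp70 values may depend on how any reads shared between such relatives were assigned, which was not examined. All 31 proteasome genes lay within 2-fold, with a median of -0.03 at percentile 21.1 (-0.23 with length centring).

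The list of carbohydrate-active enzymes, matched by name, mixes enzymes that break down plant polymers with chitinases and enzymes of fungal glucans and glycans. Of its 48 eligible members 18 were higher and 2 lower. Their median of 0.67 lay at percentile 98.5, but at 96.1 with length matching, 88.9 (0.31) with length centring, 51.3 for 6 members matched by symbol, 92.4 with a pseudocount of 5 and 81.9 with no filter on low values, where the list no longer stood apart. Without the 17 members named for chitin, 1,3-glucans or glycans, 14 of 31 were higher and 2 lower, with a median of 0.91 at percentile 99.8. This narrower list was chosen after the results were seen. The length, pseudocount and filter settings that moved the full list were not applied to it. The pectate lyase gene NCU06326 (33.4 against 0.280 RPKM) was 138-fold higher (72.8 to 303), the cellobiose dehydrogenase gene cdh-2 101-fold higher (53.3 to 222) and the xylanase gene gh10-3 19.1-fold higher (13.4 to 28.0), each from a wild-type value under 1 RPKM. These folds compare reads over library totals, which for NCU06326 and cdh-2 differ from the ratio of the RPKM values because the gene model length behind RPKM differed between libraries. By RPKM cdh-2 stood at 11.7 in the knockout and 0.297 in the wild type, a smaller ratio than 101-fold. NCU06326, cdh-2 and gh10-3 passed the filter through the knockout library alone, a selection that favours high ratios. The invertase gene inv was 8.44-fold lower (7.72 to 9.24). Among 20 plasma membrane sugar transporters, 3 were higher and 5 lower, with a median of 0.25 at percentile 48.5 (0.03 with length centring). hgt-1, annotated as a monosaccharide transporter, was 11.9-fold lower (9.94 to 14.3).

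In the list of nitrogen, sulfur and phosphate genes, 9 of 37 were higher and 7 lower. The median was -0.10 at percentile 3.89 (-0.15 at 0.93 with no filter on low values, -0.019 for members matched by symbol) and the mean 0.08. The alkaline phosphatase gene pho-2 was 16.5-fold higher (89.2 against 5.42 RPKM), the acid phosphatase gene pho-3 16.1-fold higher (12.3 to 21.6) and the phosphate transporter gene pho-5 7.99-fold higher (7.34 to 8.72). The amino acid permease gene pmg was 8.28-fold lower (7.88 to 8.71), and the nitrate and nitrite reductase genes nit-3 and nit-6 stood at 24.1 against 115 and 118 against 535 RPKM. Lipid and sterol synthesis genes stood apart on the lower side, with 6 of 35 lower, 5 higher and a median of -0.32 at percentile 0.06 (-1.11 at 0.185 for 5 members matched by symbol). The fatty acid synthase genes cel-1 and cel-2 were 2.19-fold (2.14 to 2.24) and 2.44-fold (2.40 to 2.49) lower, cel-1 short of 2-fold with length centring (-0.96), and the carotenoid gene al-1 is among the 5 higher members. Cell wall synthesis genes had a median of -0.15 at percentile 0.49, but 4.59 with length matching, 10.1 with length centring and 29.0 (-0.019) for members matched by symbol, with 3 of 39 higher and 1, the glucanosyltransferase gene gel-4, lower. DNA repair and replication genes had 4 of 46 higher and none lower, with a median of 0.28 at percentile 80.4, or 98.3 with length matching but 96.0 (0.26) with length centring, and 0.10 for members matched by symbol. csb was 3.79-fold higher (3.50 to 4.10) and mip-1, the gene of mitochondrial DNA polymerase gamma, 3.55-fold higher (3.24 to 3.89). In all, 9 of 22 lists stood apart, 4 above and 5 below, where lists of randomly drawn genes give 5%. Genes of a list can vary together between any cultures, and some lists share members, so this 5% is no error rate here. With length matching 6 of the 9 lists kept their place apart and 2 others gained it. With length centring the same 6 kept it and none gained it.

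**Figure D4:**
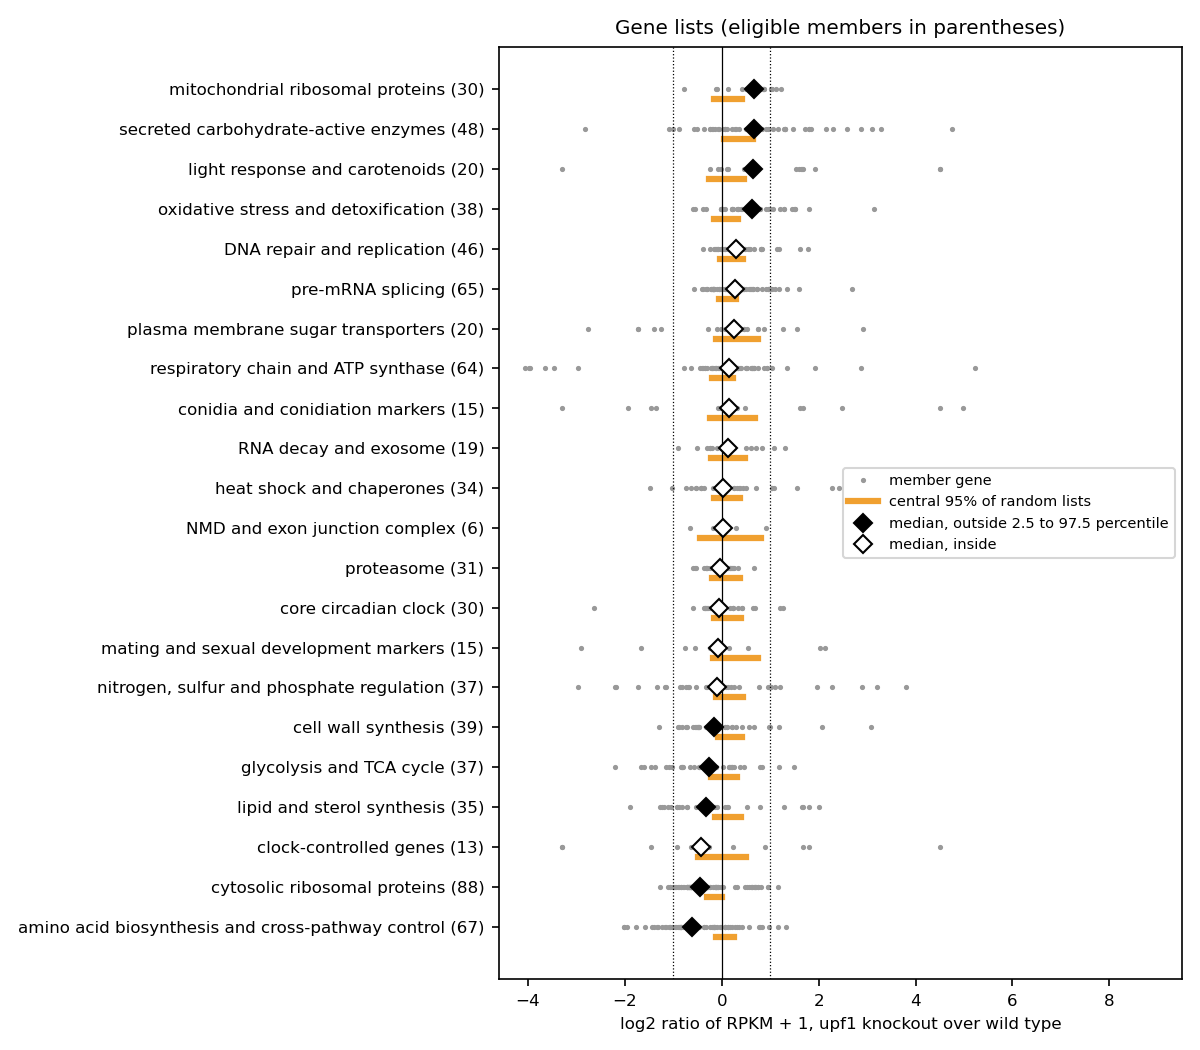
Log2 ratio of RPKM + 1, knockout over wild type (horizontal), for eligible members (grey points) of the 22 gene lists, with the median (diamond) and the central 95% of medians of 10000 expression-matched random lists (orange bar). Filled diamonds mark the 9 lists that stand apart, from amino acid biosynthesis at -0.61 to mitochondrial ribosomal proteins at 0.68.

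The largest single differences lay partly outside these groups. NCU00732, annotated as a trichothecene hydroxylase, had 179 RPKM from 16440 reads in the knockout library and 0.158 RPKM from 5 reads in the wild type, at supercontig 1 from 7386748 to 7388890. The cyanide hydratase gene NCU04697 was 114-fold higher (93.9 to 141; 289 against 2.53 RPKM). Among hypothetical protein genes NCU05628 was 119-fold higher (80.2 to 187), NCU09277 200-fold (78 to 735), NCU10865 208-fold (116 to 416) and NCU11571 126-fold (53.7 to 388), on 24, 4, 11 and 5 wild-type reads, and NCU08351, which overlaps a neighbour, was 41.5-fold higher. At the lower end, the dye-decolorizing peroxidase gene NCU09210 stood at 14.7 RPKM in the knockout and 498 in the wild type, 33.8-fold lower (32.3 to 35.5). adh-1, an alcohol dehydrogenase gene that overlaps a neighbour, was 29.4-fold lower and the chitinase gene chit-1 16.6-fold lower (15.9 to 17.3). NCU04197, a CipC protein gene, was 24.6-fold lower (18.5 to 33.3), and the hypothetical protein genes NCU05859, NCU04879 and NCU08226 were 65.3-fold, 52.2-fold and 21.1-fold lower. Genes annotated as hypothetical proteins, 3304 of the eligible genes, had 673 higher and 198 lower and a median of 0.25 above all random lists. With length matching the percentile was 95.8, and with length centring 92.5 for a median of 0.050.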

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

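The length-based, thinning, shared-length and abundant-gene settings and the narrower lists by product were chosen after the results were seen. No paired analysis was possible because each strain has 1 pooled library. For the same reason no library was left out and no other grouping was formed. Classes that need an annotation of untranslated regions were not run.

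No named gene past 2-fold and no list that stood apart changed direction under the settings run. For the genes this was a weak check, as a pseudocount keeps the sign of a ratio. The scaling and length offsets were smaller than 2-fold, so they could not reverse a gene past it. Of 749 alternative values of named genes, 437 stayed within counting error and 312 moved beyond it. Of 220 alternative percentiles of gene lists, 206 kept their side of the 2.5% bounds, although centring on the median gene shifts every gene alike and cannot change them. Genes higher numbered 2120 at 1.5-fold, 285 at 4-fold and 774 with eligibility at 20 RPKM, and genes lower 937 at 1.5-fold and 99 at 4-fold, as looser and stricter rules must give. The median log2 ratio of eligible genes was 0.13 with a pseudocount of 5, 0.13 at 20 RPKM, -0.020 with TMM scaling (factors 1.07 for the knockout and 0.934 for the wild type) and 0.22 without the 2 most abundant genes. The log2 ratio of prd-6 (upf1), -2.65, was -2.98 and -1.83 with pseudocounts of 0.1 and 5, -2.80 after median centring and -2.82 with TMM scaling.

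With random lists also matched on length, glycolysis and TCA (-0.25, percentile 5.24), carbohydrate-active enzymes (0.67, 96.1), cell wall synthesis (-0.15, 4.59) and hypothetical proteins (0.25, 95.8) no longer stood apart, while clock-controlled genes (-0.43, 0.75) and DNA repair (0.28, 98.3) did. With ratios centred within length bins none of these 6 did: glycolysis and TCA (-0.39, 6.55), carbohydrate-active enzymes (0.31, 88.9), cell wall synthesis (-0.14, 10.1), hypothetical proteins (0.050, 92.5), clock-controlled genes (-0.67, 5.35) and DNA repair (0.26, 96.0). Mitochondrial ribosomal proteins (0.30, 99.7), oxidative stress (0.28, 99.9) and cytosolic ribosomal proteins (-0.79) still did, and 844 of the 1214 higher and 401 of the 407 lower genes kept their calls. In all, length centring gave 849 genes higher and 599 lower, so the lower set also gained genes outside the 407. Median centring gave 978 higher and 547 lower, and TMM scaling 963 and 576. Carbohydrate-active enzymes also lost their place with a pseudocount of 5 (0.39, 92.4), with no filter (0.34, 81.9) and with the 6 members matched by symbol (0.40, 51.3), and cell wall synthesis with the 7 members matched by symbol (-0.019, 29.0), while the 8 such members of glycolysis and TCA (-1.42, below all random lists), 8 of oxidative stress (1.03, 99.8) and 5 of lipid synthesis (-1.11, 0.185) had larger medians. Glycolysis and TCA also lost it with the 26 enzymes of the pathways (-0.12, 19.9). Nitrogen, sulfur and phosphate genes gained it with no filter (-0.15, 0.93). Apart from the length settings and the smaller lists, the cause was not tested. Depth limits genes below a few RPKM: a ratio that rests on a handful of wild-type reads has a wide interval, as for NCU00732 with 5 wild-type reads (698 to 5017).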

Other observations

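The tests of centring within length bins, of counting error, of length over the 28 mitochondrial genes, of library quality, of poly(A) selection and of introns were chosen after the results were seen.

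Both libraries were led by the thiamine synthesis genes nmt-1 and NCU06110, a thiazole biosynthetic enzyme, both picked after their read shares were seen. nmt-1 took 6.87% of knockout reads and was 2.27-fold higher in the knockout library, and NCU06110 took 4.13% of knockout reads and 2.93% of wild-type reads. On the supercontig of mitochondrially encoded genes, 8 of the 9 eligible genes were at least 2-fold lower in the knockout library, and 26 of all 28 had a ratio below 1. The 3 mating-type A genes matA-1, matA-2 and matA-3 had 0 reads in both libraries.

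Genes past 2-fold also lay side by side. There were 302 adjacent, non-overlapping pairs that differed in the same direction, against a median of 171 and a highest value of 219 over 10000 shuffles of the ratios, so chance placement is argued against. Of these pairs 251 were higher and 51 lower, and 182 lay on the same strand. Among all eligible genes 16.5% were higher and 5.52% lower, so more higher pairs arise from the shares alone. The shuffles were not split by direction or strand, so these counts do not show which kind of pair exceeded chance more. The longest run held 6 genes, NCU10538 to NCU09992 on supercontig 7 from 3939172 to 3951975, with a median log2 ratio of 1.92. A run of 4 genes around the pectate lyase gene NCU06326 on supercontig 4, from 2905252 to 2915694, had a median of 2.62, and a run of 4 on supercontig 4 from 6553 to 21754, with a median of 1.42, holds the polyketide synthase gene pks-5. Reads running on from one gene into the next were not tested as a source.

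The first pattern weighed is that more genes were higher than lower in the knockout library, 2.98 per gene lower. The 2 most abundant genes take a larger share of the knockout library, which lowers the knockout values of all other genes. Without them the excess was 3.745, so they work against it. The counting interval excluded a ratio of 1 for 1214 of 1214 higher and 403 of 407 lower genes. Among these the excess was 3.012, which argues against counting error. Thinning the knockout reads gave 3.002 but changed only 68 of 1621 calls, as RPKM is scaled to depth already, so it decides nothing, and with 1 library per strain any other effect of the greater depth cannot be told apart from one of the strain. Centring on the median gene left 1.788, above the bound of 1.5 set beforehand, and TMM scaling left 1.672. Offsets of these sizes may thus account for part of the excess but not for all of it. A larger shared offset was not tried, so a single offset is not excluded as the source of all of it. Centring within length bins, which removes the median offset as well, brought it to 1.417, so the length trend together with an offset is a candidate explanation for much of it. A loss of decay without UPF1 would also leave more transcripts higher and was not tested apart from these.

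The second pattern is the length trend itself, a gap of 0.50 in median log2 ratio between the shortest and the longest of 4 equal groups of gene models. Within 5 bins of expression the gap went from 0.8342 in the lowest bin to 0.4142 in the highest. Its size thus went with expression level, but its presence in every bin argues against expression level as its only source. The 6589 genes in no list had a gap of 0.5235, which argues against the lists. A library or RNA quality difference that acts on length remains open, since with 1 library per strain it cannot be told apart from an effect of the strain. The same holds for a biological difference in the decay of short transcripts, which was not tested.

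The third pattern is the lower level of mitochondrial transcripts, 910 reads in the knockout against 6045 in the wild type over 28 genes, 13.4-fold lower relative to totals (12.5 to 14.4). Some of these gene models overlap, so the sum may count reads more than once, and it pools genes with unequal ratios. Over all 28 the median log2 ratio was -1.34, and after subtracting the median of their length bins -1.891 (95% interval by rank -2.46 to -1.27), which argues against the length trend as the whole cause. That interval takes the genes as independent, although some models overlap and all lie on the same supercontig, so it may be too narrow. The 9 eligible genes, with a median of -3.47, passed the filter through the wild-type library alone, a selection that favours low ratios. A lower share of mitochondrial RNA carried through poly(A) selection remains open and, with 1 library per strain, cannot be told apart from an effect of the strain. In the same libraries aod-1 was higher, and the list of mitochondrial ribosomal proteins stood apart on the higher side by its median. The share of its members past 2-fold, 5 of 30, was close to the 16.5% of all eligible genes. A hypothesis that these mitochondrial differences belong to a single response to the knockout was not tested.

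Whether gene models with introns differed from those without was asked because exon junctions can mark transcripts for decay. The 5813 intron-containing models had a median of 0.15, at percentile 99.56 of lists matched on expression and length, but those lists spanned only 0.12 to 0.14 and the 1400 intron-free models had a higher unmatched median, 0.19, although fewer of them were at least 2-fold higher (14.6% against 16.7%, also unmatched). A difference of this size may come from imperfect matching on length, and intron position relative to the stop codon was not analysed here.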
